A study of Drosophila melanogaster with 6 samples.

How the data were processed

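RNA from whole larvae of Drosophila melanogaster was measured on 6 single-channel Affymetrix arrays, 3 from larvae on a semi-purified diet and 3 from larvae on the same diet with palm fruit juice. Per the labels' protocols, total RNA was isolated with a Qiagen RNeasy kit, and biotinylated single-stranded cDNA was prepared from 100 ng of it with the GeneChip WT PLUS reagents. The deposited values are log2 expression values, 1 per array row, and the submitters' processing notes name RMA and Affymetrix Expression Console 1.4.0.38. The log2 scale was checked on the deposited values, which ran from 1.44 to 12.97 with array medians of 3.60 to 3.77. RMA as generally defined corrects background, brings the probe distributions of all arrays together and summarises probes, so that a shift of most transcripts in 1 direction would largely be removed. The order of the steps, any filter and the annotation version are not given in the sources used here.

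The value table held 16322 rows with no missing value. The platform's annotation gave 1 gene for 13440 rows, several genes for 555 and no gene for 2327. Of the rows with 1 gene, 13063 were found by identifier in a gene table of the fly assembly Release 6 plus ISO1 MT, 377 kept the name of the annotation, and 1 was renamed to its current symbol. That table served for names and gene length only. These rows held 13402 genes, 36 of them with several rows, of which the row with the highest mean over all arrays was kept. The 25% of genes with the lowest mean over all arrays, those below a log2 value of 2.63, were left out, and 10051 genes were tested. Rows with several genes or none were left out of the comparison, since no single gene could be named.

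Arrays were grouped by the labels. The groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with no covariate, and p-values were adjusted by Benjamini-Hochberg over all tested genes. A difference is the mean log2 value of the juice arrays minus that of the control arrays, and a fold is the corresponding ratio. Errors of group means are SDs over 3 arrays, and errors of differences are limma's moderated standard errors. Each array held RNA of 3 to 4 larvae, per the labels, and the p-values measure only the spread between these pools, which may in part be technical. The replicate number was not used as a block, since the labels do not say that a number is shared across groups.

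Gene lists for metabolism, detoxification, immunity, digestion, moulting, hormones, growth and the organs of a larva were compared with all other tested genes by camera in limma, with its preset inter-gene correlation of 0.01, two-sided. Of 39 lists, 38 had at least 3 tested genes, and their p-values were adjusted over these 38 lists. Beside it, camera with the correlation estimated from the data was run, as well as fry, which tests whether the genes of a list move on balance 1 way and does not compare them with other genes. For each list, the mean of its genes per array was compared between the groups by a two-sided exact permutation test, which with 3 arrays against 3 cannot go below p = 0.1. A name that matched no row with exactly 1 gene was not used, so some lists cover their family in part.

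The genes named in the text follow a rule. It took the 12 genes with the largest increase and the 12 with the largest decrease among those past adjusted p under 0.05 with no overlap between the groups. Where fewer passed, it took the genes of that direction with the smallest unadjusted p up to 12, which are then said not to pass. For each list described, up to 4 members with the smallest unadjusted p were named. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were each array left out in turn, the replicate number as a block, other filters on dim genes, quantile normalization, equal array medians, another variance model, array weights, averaged rows per gene, all rows, no moderation, other thresholds and other list tests. Leaving out control replicate 1 and palm fruit juice replicate 2 together, and repeating the alternatives for the count at unadjusted p, were chosen after seeing the data.

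The procedure was tested on simulated data drawn from the spread of these arrays, with 200 of 10051 genes changed in each of 20 runs. It recovered 2.39% of genes changed by 0.50 on the log2 scale, 56.3% of those changed 2-fold and 97.0% of those changed 4-fold, and 5.53% of its calls were false. A list of 16 genes shifted by 0.50 on the log2 scale was called in 100% of 20 runs. All genes were drawn independently of each other in these runs, with normal noise, and all sizes of change were mixed in each run. The adjustment loosens as more genes change strongly, so recovery of the smaller changes rests in part on the 4-fold genes. In the arrays the same list, glycolysis, had an estimated inter-gene correlation of 0.62. The simulated rates of recovery and of false calls therefore do not carry over to the list calls. For single genes the rates hold for these simulated settings only and are no measure of the power in these arrays. For arrays no read depth applies, and the number of arrays limits the precision.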

Results

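Larvae of the laboratory strain w1118 were raised from the egg for 5 days on a semi-purified diet, with or without palm fruit juice, an aqueous preparation of oil palm fruit rich in phenolic compounds. Per the labels, 4 ml of juice brought the diet to 19000 mg of gallic acid equivalents per kg, or 0.86 mg per kcal; both cannot hold, since together they imply 22093 kcal per kg of diet, and the dose was not used here. Each group had 3 arrays, and each array held whole-body RNA from 3 to 4 larvae. Pearson correlations across genes were 0.959 to 0.981 between control arrays, 0.955 to 0.975 between juice arrays and 0.940 to 0.984 between arrays of different groups. The ranges within and between groups overlapped. A pair of arrays stood apart: 536 genes in control replicate 1 and 440 in palm fruit juice replicate 2 lay at least 2-fold from the mean of the other arrays, against 54 to 178 in the rest.

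The comparison asked which transcripts differed between larvae fed with and without palm fruit juice. Genes of energy metabolism lay higher in juice-fed larvae as groups, mainly through palm fruit juice replicates 1 and 2. A higher mean was seen in 39 of 41 subunits of oxidative phosphorylation and 15 of 16 genes of a glycolysis list. The glycolysis list also held genes of glycogen and glucose synthesis. In a citric acid cycle list, which also held a pyruvate dehydrogenase subunit, 14 of 14 genes had a higher mean. Genes within these lists moved together across arrays (estimated correlations of 0.56, 0.62 and 0.27), so the counts are not independent evidence. In palm fruit juice replicate 3 the glycolysis and citric acid cycle means, -0.19 and -0.12 relative to all arrays, lay within the control range. Muscle genes, larval cuticle proteins and cytochrome P450s of the xenobiotic families were also higher as groups, but less evenly. Of their members 11 of 17, 16 of 26 and 21 of 37 were higher. The muscle call rested on palm fruit juice replicate 1, without which the mean log2 difference was 0.017. The calls of larval cuticle proteins and cytochrome P450s ended without control replicate 1 or without palm fruit juice replicate 1. Genes of the response to the moulting hormone ecdysone were lower, 14 of 18 with a lower mean, as were testis genes and nervous system genes. Testis genes were lower only with control replicate 1, without which their mean log2 difference was 0.11. Nervous system genes leaned on palm fruit juice replicate 2, without which their mean log2 difference was -0.12. The 9 lists named here, of 38 tested, passed camera at adjusted p under 0.05 with its preset correlation. With an estimated correlation camera called 0 lists (smallest adjusted p = 0.887 with an estimated correlation) and 0 at unadjusted p under 0.05, and fry likewise called 0 (smallest adjusted p = 0.950) and 0 at unadjusted p under 0.05. No single gene passed limma's test.

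Among the 12 genes with the smallest unadjusted p on the higher side, the largest differences were those of Mpcp1, a mitochondrial phosphate carrier, and Sodh2, a sorbitol dehydrogenase. Mpcp1 measured 6.23 ± 0.52 in control and 8.13 ± 0.79 in juice larvae (log2, mean ± SD, n = 3 per group), a 3.74-fold difference. Sodh2 measured 4.53 ± 0.22 and 5.81 ± 0.57, a 2.42-fold difference. The other genes of this side were CG14273, CG10433, CG17029, CG17751, CG14292, CG17108, CG34301, salt, CG12206 and CG17826, and the folds of all 12 ran from 1.55 to 3.74. On the lower side, Kah, a transcription factor of the Snail family, measured 6.48 ± 0.28 in control and 5.46 ± 0.25 in juice larvae, a log2 difference of -1.03 ± 0.20 (SE). LanA, a laminin subunit of basement membranes, differed by -0.66 ± 0.18, the serpin Spn43Aa by -0.91 ± 0.24 and CG4950 by -1.24 ± 0.29. The remaining genes of this side were mthl2, NimA, CG31368, CG32437, CG42566, prage, CG5509 and Rab9Fa, with control-over-juice folds of 1.48 to 2.36 over all 12. In all 24 genes the juice arrays lay wholly above or wholly below the control arrays, which largely follows from choosing the smallest p. None passed: limma's adjusted p was 0.931 for each.

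**Figure D1:**
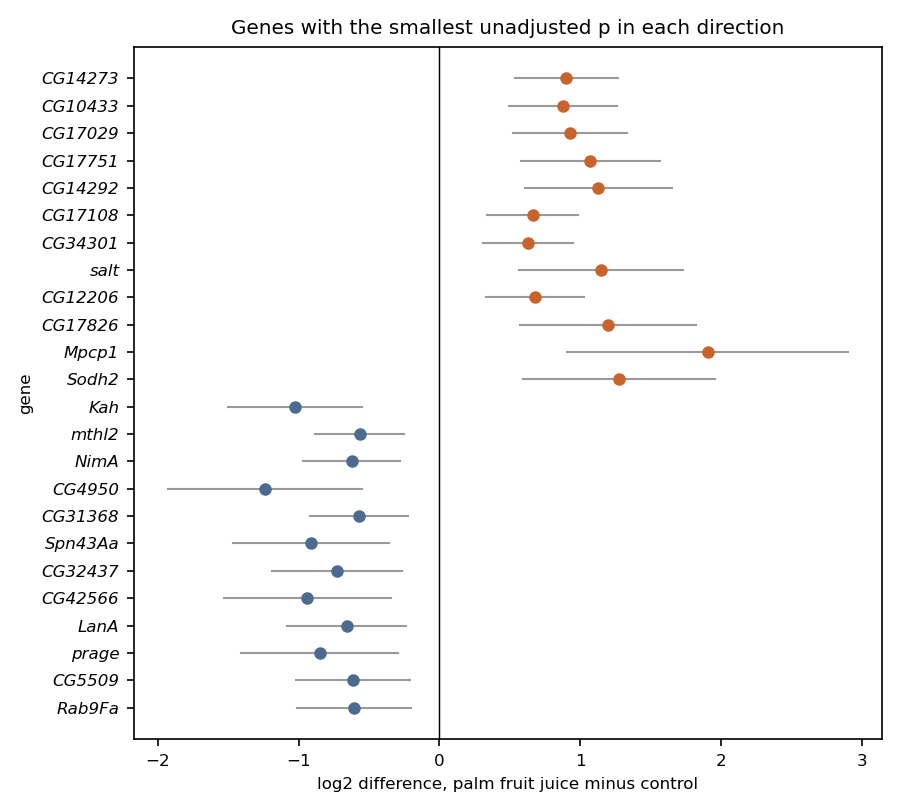
Log2 difference, palm fruit juice minus control, of the 24 genes with the smallest unadjusted p in each direction (3 arrays per group). Points are differences and lines their 95% intervals from limma's moderated errors; values run from -1.24 for CG4950 to 1.90 for Mpcp1, and no gene passed the adjusted threshold.

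Across all 10051 genes, limma called 0 at adjusted p under 0.05 (smallest adjusted p = 0.931), and the ordinary test without moderation also called 0. At unadjusted p under 0.05, limma gave 470 genes, 269 higher and 201 lower, where 502.6 would arise by chance, and the unmoderated test gave 399. With 1 array left out the count ran from 181, without control replicate 3, to 750, without palm fruit juice replicate 1. The balance turned without control replicate 2 (266 higher, 307 lower), juice replicate 2 (176 higher, 182 lower) and control replicate 1 and juice replicate 2 together (175 higher, 279 lower). Of the 470, 57.2% were higher, a share of 68.2% after quantile normalization and 75.1% with equal array medians. The groups did not overlap in 1011 genes, 10.1% of those tested, where chance gives 10%. The juice and control means differed at least 2-fold in 115 genes, 66 higher and 49 lower. The median moderated standard error of a difference was 0.18 on the log2 scale. Without palm fruit juice replicate 3, limma called 4 genes, all higher: the cuticle protein gene Cpr47Ec, with the smallest adjusted p (0.00154), CG9757, CG7299 and Vajk2, named after their values were seen. The smallest adjusted p under the other alternatives ran from 0.504 to 0.998.

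Oxidative phosphorylation subunits had a mean log2 difference of 0.33 over 41 genes (camera, adjusted p = 1.91e-14). The adjusted p was 0.887 with an estimated correlation, which came to 0.563 between the genes of the list. The mean of the list was higher in each of 3 juice arrays than in any control array, but juice replicate 3, at -0.098 relative to all arrays, stood close to control replicate 2, at -0.12. The list held 9 members at unadjusted p under 0.05, all higher. ND-39 of complex I measured 4.70 ± 0.11 in control and 5.39 ± 0.31 in juice larvae (n = 3 per group), Cyt-c1 of complex III 7.48 ± 0.11 and 8.14 ± 0.42, and COX8 of complex IV 7.30 ± 0.31 and 8.06 ± 0.40. UQCR-11, also of complex III, measured 4.87 ± 0.02 and 5.42 ± 0.26. Without palm fruit juice replicate 2, the array furthest out in this list, the mean difference was 0.19 and the call remained (adjusted p = 8.88e-08).

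The glycolysis list, in which lactate dehydrogenase had no usable value, had a mean log2 difference of 0.54 over 16 genes (camera, adjusted p = 1.16e-09; adjusted p = 0.887 with an estimated correlation). Of its 5 members at unadjusted p under 0.05, all higher, Glys (glycogen synthase) and UGP (UDP-glucose pyrophosphorylase) serve glycogen synthesis and Gpdh1 (glycerol-3-phosphate dehydrogenase) lies beside the glycolytic path. Gpdh1 measured 6.46 ± 0.51 in control and 7.40 ± 0.50 in juice larvae, the aldolase gene Ald1 7.51 ± 0.11 and 8.05 ± 0.36, Glys 7.13 ± 0.15 and 7.63 ± 0.12, and UGP 5.56 ± 0.11 and 6.02 ± 0.27 (n = 3 per group). The 14 genes of the citric acid cycle list had a mean difference of 0.24 (camera, adjusted p = 0.000811; adjusted p = 0.887 with an estimated correlation), with 0 members at unadjusted p under 0.05. SdhD, a succinate dehydrogenase subunit, differed by 0.37 ± 0.19, muc, a pyruvate dehydrogenase subunit, by 0.38 ± 0.21, and mAcon1 and Idh3b by 0.31 ± 0.18 and 0.33 ± 0.20. The citric acid cycle call ended without palm fruit juice replicate 1 (mean 0.22, adjusted p = 0.116), and the mean was 0.14 without juice replicate 2 and 0.36 without juice replicate 3. In palm fruit juice replicate 3 the means of both lists, -0.19 and -0.12 relative to all arrays, lay within the range of the control arrays.

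Muscle genes had a mean log2 difference of 0.20, with 11 of 17 higher (camera, adjusted p = 0.00088; adjusted p = 0.887 with an estimated correlation). The 6 members at unadjusted p under 0.05 were all higher. They included the myosin light chains Mlc1, at 10.55 ± 0.18 in control and 11.15 ± 0.23 in juice larvae, and Mlc2, at 11.09 ± 0.25 and 11.74 ± 0.25 (n = 3 per group). The troponin T gene up differed by 0.62 ± 0.22 and Mf, a thick filament protein, by 0.57 ± 0.22. The call rested on palm fruit juice replicate 1: without it the mean difference was 0.017 (adjusted p = 0.839), and without juice replicate 3 it was 0.35.

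**Figure D2:**
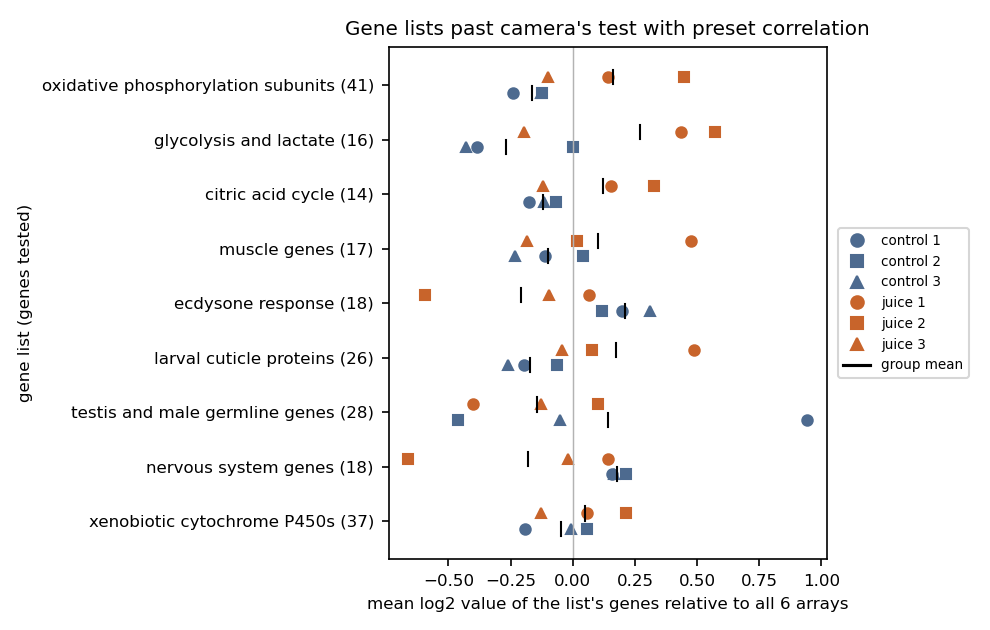
Mean log2 value of each list's genes in each of the 6 arrays, relative to the mean over all arrays, for the 9 lists past camera's test with preset correlation. Circles, squares and triangles are replicates 1, 2 and 3, blue for control and orange for palm fruit juice, and black bars are group means; the testis list stands at 0.94 in control replicate 1, and the ecdysone response list at -0.59 in juice replicate 2.

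Ecdysone response genes had a mean log2 difference of -0.42 over 18 genes (camera, adjusted p = 0.00304; adjusted p = 0.887 with an estimated correlation), and the 4 members at unadjusted p under 0.05 were all lower. Blimp-1, an ecdysone-induced transcriptional repressor, measured 6.22 ± 0.27 in control and 4.76 ± 0.95 in juice larvae, and the nuclear receptor gene Hr4 6.82 ± 0.88 and 5.07 ± 1.26 (n = 3 per group). ImpE1 and ImpE2, ecdysone-inducible genes of imaginal discs, differed by -0.93 ± 0.28 and -0.64 ± 0.22. The mean of the list was lower in every juice array than in every control array, with juice replicate 1, at 0.065 relative to all arrays, the closest to control replicate 2, at 0.12. Without palm fruit juice replicate 2 its mean difference was -0.22 (adjusted p = 0.0659).

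Larval cuticle proteins had a mean log2 difference of 0.35 and a median of 0.11, with 16 of 26 higher (camera, adjusted p = 0.0316; adjusted p = 0.887 with an estimated correlation). The mean leaned on a few genes: Lcp9 measured 8.34 ± 1.31 in control and 11.03 ± 0.51 in juice larvae, a 6.47-fold difference, and Lcp65Ac 6.24 ± 0.48 and 7.46 ± 0.53 (n = 3 per group). Lcp65Af and Lcp65Ae, near the dim end of the scale in control at 2.50 ± 0.17 and 2.50 ± 0.24, differed by 1.33 ± 0.49 and 1.04 ± 0.39. All 6 members at unadjusted p under 0.05 were higher. The call ended without control replicate 1 (mean 0.34, adjusted p = 0.124), without palm fruit juice replicate 1 (mean 0.19, adjusted p = 0.771), and with no filter on dim genes (mean 0.19, adjusted p = 0.238) or the dimmer 50% removed (mean 0.47, adjusted p = 0.232).

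**Figure D3:**
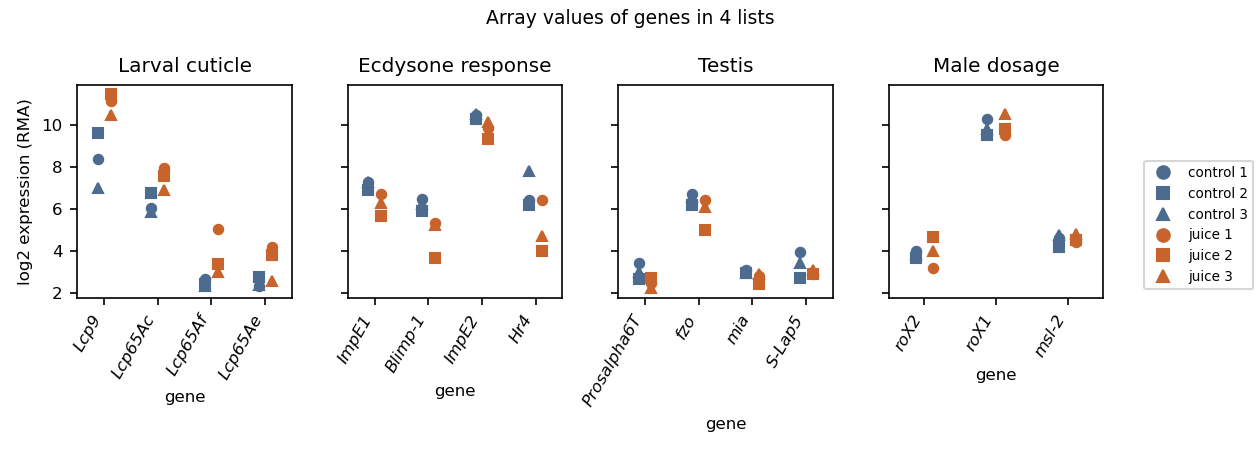
Log2 expression in each of the 6 arrays of genes from 4 lists: larval cuticle, ecdysone response, testis, and the male dosage compensation genes roX1, roX2 and msl-2. Circles, squares and triangles are replicates 1, 2 and 3, blue for control and orange for palm fruit juice; Lcp9 lies between 6.99 and 9.62 in control and between 10.48 and 11.47 in juice larvae, while roX1 and roX2 overlap between the groups.

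Lists that stand for organs or sex moved in part with single arrays. Testis genes had a mean log2 difference of -0.29, with 23 of 28 lower (camera, adjusted p = 0.0401; adjusted p = 0.917 with an estimated correlation), and 1 member at unadjusted p under 0.05, Prosalpha6T, a testis-specific proteasome subunit, at 3.06 ± 0.38 in control and 2.48 ± 0.24 in juice larvae. The mitofusin gene fzo differed by -0.66 ± 0.35, mia by -0.29 ± 0.17 and S-Lap5 by -0.39 ± 0.30. Without control replicate 1 the direction turned (mean 0.11, adjusted p = 0.310). The call also ended without palm fruit juice replicate 1 (mean -0.16, adjusted p = 0.267) or juice replicate 3 (mean -0.29, adjusted p = 0.118) and with the dimmer 50% removed (mean -0.42, adjusted p = 0.125), and the mean was -0.59 without control replicate 2. The male dosage compensation genes did not pass (3 of 3 higher, mean 0.08, adjusted p = 0.682): roX1 measured 9.88 ± 0.39 in control and 9.96 ± 0.51 in juice larvae (n = 3 per group). Ovary genes did not pass (adjusted p = 0.682), and their mean of 0.04 and median of -0.04 differed in sign.

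Nervous system genes had a mean log2 difference of -0.36 and a median of -0.22, with 14 of 18 lower (camera, adjusted p = 0.0401, and 0.887 with an estimated correlation). The 4 higher members were Gad1, elav, VGlut and VAChT, with differences of 0.01 to 0.21. CadN, the neuronal cadherin and the only member at unadjusted p under 0.05, measured 4.75 ± 0.11 in control and 3.68 ± 0.66 in juice larvae (n = 3 per group). The tyrosine hydroxylase gene ple, which also serves cuticle tanning, differed by -2.18 ± 1.19, the potassium channel gene Sh by -0.58 ± 0.36 and the glial gene repo by -0.25 ± 0.16. The call ended without palm fruit juice replicate 2 (mean -0.12, adjusted p = 0.655), control replicate 1 (-0.37, adjusted p = 0.0836) or control replicate 2 (-0.34, adjusted p = 0.243), with no filter on dim genes (-0.33, adjusted p = 0.0816) and after quantile normalization (-0.32, adjusted p = 0.0538). Salivary glue and late puff genes did not pass (adjusted p = 0.215); their mean of 0.10 lay above 0 and their median of -0.20 and camera's direction below, and Sgs4 and Eig71Ee, members at unadjusted p under 0.05, differed by -0.60 ± 0.19 and -0.60 ± 0.22. Larval serum and fat body proteins (mean -0.06, adjusted p = 0.341) and midgut serine proteases (mean 0.06, adjusted p = 0.518) did not pass either. The proteases passed without control replicate 2 (mean 0.16, adjusted p = 0.0138), but not with an estimated correlation and all arrays (adjusted p = 0.958).

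Among detoxification genes, 37 cytochrome P450s had a mean log2 difference of 0.10, with 21 higher (camera, adjusted p = 0.0401; adjusted p = 0.887 with an estimated correlation). Its 3 members at unadjusted p under 0.05, Cyp317a1, Cyp12e1 and Cyp9c1, differed by 0.44 ± 0.16, 0.52 ± 0.21 and 0.48 ± 0.20, and Cyp6a14 by 0.40 ± 0.18. The call ended without control replicate 1 (mean 0.02, adjusted p = 0.721), palm fruit juice replicate 1 (0.09, adjusted p = 0.546) or juice replicate 2 (0.01, adjusted p = 0.501), and after quantile normalization (0.12, adjusted p = 0.0538), with equal array medians (0.13, adjusted p = 0.0598) or with the dimmer 50% removed (0.09, adjusted p = 0.261). The mean was 0.15 without control replicate 2 and 0.18 without juice replicate 3. Its direction turned with array weights (mean -0.0035, adjusted p = 0.874) and without control replicate 1 and juice replicate 2 together (mean -0.060, adjusted p = 0.697). Glutathione S-transferases did not pass (mean 0.08, adjusted p = 0.147), with GstE1 at 5.02 ± 0.27 in control and 5.74 ± 0.29 in juice larvae (n = 3 per group), nor did UDP-glucuronosyltransferases (mean 0.03, adjusted p = 0.341), where Ugt49B1 differed by 0.63 ± 0.19. Glutathione S-transferases passed without control replicate 2 (mean 0.14, adjusted p = 0.0164), and metal handling genes without control replicate 3 (mean 0.15, adjusted p = 0.0299); both had adjusted p = 0.887 with an estimated correlation and all arrays. Antioxidant enzymes did not pass (mean 0.08, adjusted p = 0.257): the immune-regulated catalase gene Irc differed by -0.43 ± 0.18, the main catalase gene Cat by -0.24 ± 0.14 and Gclm of glutathione synthesis by 0.42 ± 0.19. Metal and iron handling genes (mean 0.09, adjusted p = 0.206), endoplasmic reticulum chaperones (mean 0.03, adjusted p = 0.601) and heat shock proteins (adjusted p = 0.955) did not pass. For heat shock proteins the mean was -0.02 and the median 0.06, and camera's direction was up as deposited and down after quantile normalization. Hsp26 differed by -0.71 ± 0.28.

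Of the other lists that did not pass, the proteasome came closest, with 22 of 26 genes lower (mean -0.12, camera's adjusted p = 0.0782) and a difference of -0.35 ± 0.15 in Rpn1. Its adjusted p was 0.917 with an estimated correlation and 0.952 by fry. With the preset correlation it passed under 5 alternatives: without control replicate 2 (mean -0.20, adjusted p = 0.0113), without palm fruit juice replicate 2 (-0.25, adjusted p = 2.31e-06), without control replicate 1 and juice replicate 2 together (-0.26, adjusted p = 0.000145), after quantile normalization (-0.12, adjusted p = 0.0236) and with array weights (-0.16, adjusted p = 0.00621). Chitin and peritrophic matrix genes (mean 0.07, adjusted p = 0.195) held 5 members at unadjusted p under 0.05, all higher, among them Peritrophin-A, obst-E and Gasp with differences of 0.74 ± 0.22, 1.49 ± 0.46 and 1.08 ± 0.35. They passed without control replicate 2 (mean 0.16, adjusted p = 0.0138) or juice replicate 3 (0.19, adjusted p = 0.00855), against adjusted p = 0.910 with an estimated correlation and all arrays. In lipid digestion and lipolysis (mean 0.06, adjusted p = 0.245) the acyl-CoA oxidase gene Acox57D-p differed by 0.62 ± 0.18, while lipid synthesis (mean 0.10, adjusted p = 0.203) and carbohydrate digestion (mean 0.13, adjusted p = 0.341) had 0 such members. Without control replicate 2, lipid digestion (mean 0.12, adjusted p = 0.0211) and carbohydrate digestion (0.35, adjusted p = 0.00174) passed, and without juice replicate 3 lipid synthesis (0.19, adjusted p = 0.0113). With an estimated correlation and all arrays their adjusted p was 0.917, 0.917 and 0.887. Melanisation and haemocyte genes (mean -0.15, adjusted p = 0.341) included yellow-f, with a difference of -0.80 ± 0.29, and Ddc, the dopa decarboxylase gene, with -0.76 ± 0.28. Peptidoglycan recognition proteins and lysozymes had a mean of -0.19 (adjusted p = 0.341). Antimicrobial peptides (adjusted p = 0.961) had a mean of 0.07, a median of -0.02 and a downward direction in camera, and Drsl1 and Drsl2 differed by -0.44 ± 0.14 and 1.20 ± 0.56. No Turandot stress gene stood above the filter, so that 0 were tested.

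Of the growth and hormone lists, cytosolic ribosomal proteins (mean 0.06, adjusted p = 0.199), DNA repair (mean -0.07, adjusted p = 0.630), juvenile hormone genes (mean -0.01, adjusted p = 0.955), autophagy genes (mean 0.00066, adjusted p = 0.682) and the circadian clock (mean 0.0019, adjusted p = 0.961) did not pass. Ribosomal proteins passed without control replicate 3 (mean 0.11, adjusted p = 0.0151) or juice replicate 3 (0.12, adjusted p = 0.00855), and DNA repair without juice replicate 3 (-0.18, adjusted p = 0.0321). With an estimated correlation and all arrays their adjusted p was 0.931 and 0.964. Camera's direction was up, relative to all other genes, and the mean below 0 for ecdysone synthesis (-0.03, adjusted p = 0.682), insulin and TOR signalling (-0.06, adjusted p = 0.771), amino acid metabolism (-0.01, adjusted p = 0.682), DNA replication (-0.0089, adjusted p = 0.781) and ribosome biogenesis (-0.02, adjusted p = 0.955). Their medians lay above 0, except for ribosome biogenesis (-0.04). Amino acid metabolism passed as higher without juice replicate 3 (mean 0.13, adjusted p = 0.0150) and as lower without control replicate 1 and juice replicate 2 together (-0.20, adjusted p = 0.0445), against adjusted p = 0.973 with an estimated correlation and all arrays. Within these, the sestrin gene Sesn differed by -0.55 ± 0.17 and the homogentisate dioxygenase gene hgo by 0.92 ± 0.32.

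In the 38 lists, 0 members passed limma's test adjusted over all genes, and 0 lists had a member that passed when adjusted over the list alone. The exact permutation test of list means gave p = 0.1, the smallest it allows, for oxidative phosphorylation, ecdysone response, larval cuticle and nervous system genes. By chance 10% of lists would reach that p with 3 arrays against 3, about the share seen here, so it adds no support for these lists. It gave exact p = 0.2 for glycolysis, 0.3 for the citric acid cycle, 0.4 for cytochrome P450s, 0.5 for muscle and 0.7 for testis genes. With array weights, which counted palm fruit juice replicate 2 at 0.421, camera called oxidative phosphorylation at a mean of 0.20 (adjusted p = 1.60e-06), glycolysis at 0.34 (adjusted p = 8.77e-05) and ecdysone response at -0.34 (adjusted p = 0.00885) among the 9. Without control replicate 1 and juice replicate 2 together it called oxidative phosphorylation at a mean of 0.15 (adjusted p = 0.00057), glycolysis at 0.33 (adjusted p = 0.000876), muscle at 0.24 (adjusted p = 0.00636) and larval cuticle at 0.38 (adjusted p = 0.0187). These calls rest on the preset correlation: with all arrays, each of these 5 lists had adjusted p = 0.887 with an estimated correlation. Outside the 9, array weights gained the proteasome, lower, and the joint removal the proteasome and amino acid metabolism, both lower. For the 11 lists gained under any alternative, camera's adjusted p with an estimated correlation was 0.887 to 0.973 with all arrays.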

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

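Repeats of the count at unadjusted p under the alternatives, and leaving out control replicate 1 and palm fruit juice replicate 2 together, were chosen after the result was seen. Limma's count of genes past adjusted p was 0 under the alternatives run, except 4 without palm fruit juice replicate 3, and 247 where unadjusted p with a 1.5-fold change was asked instead. With the replicate number as a block it was 0, with 484 genes at unadjusted p and 9 lists, and deviations of same-numbered arrays correlated at -0.11, -0.07 and -0.08 across genes. With 1 array left out, genes past adjusted p ran from 0 to 4, genes at unadjusted p from 181 (without control replicate 3) to 750 (without juice replicate 1), and lists called from 4 to 14. The lists were 4 without juice replicate 1, 5 without control replicate 1, 14 without control replicate 2, 4 with array weights, and 0 with an estimated correlation or by fry. All rows gave 740 genes at unadjusted p, with more rows tested. Without control replicate 1 and juice replicate 2 together, limma gave 0 genes past adjusted p, 454 at unadjusted p and 6 lists. The mean of the testis list ran from -0.59 to 0.11 with 1 array left out, turning without control replicate 1, and that of cytochrome P450s to -0.0035 with array weights and -0.060 without control replicate 1 and juice replicate 2 together; the cause was not tested for cytochrome P450s. Of 153 list values under alternatives, 102 kept direction and side of the threshold and 48 lost the call. All 380 values of the 24 named genes kept their direction without passing (smallest adjusted p 0.146). The groups lay wholly apart in each of these genes, so leaving out, weighting or blocking arrays could not turn the direction. The kept direction is therefore no support. Of these genes, 4 lay under the stricter filter and have no value there. Detection calls were not used here, and the filter on the mean value alone set which dim genes were tested.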

Other observations

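Genes that split the juice arrays or were high in control replicate 3 were picked after their values were seen. So were the tests of larval stage, of palm fruit juice replicate 2 alone and of male larvae. The tests of a shift of the whole array and of the length trend in juice replicate 2 were also chosen then. The other tests were planned before, but the lists pooled for the test of gene length were picked after they were called higher.

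Several genes with large differences split the juice arrays. Cpr47Ec, a cuticle protein gene, stood at 8.49 and 8.56 in palm fruit juice replicates 1 and 2 and at 3.30 in replicate 3, against 2.81 to 3.30 in control larvae. Without replicate 3 it differed by 5.50 ± 0.19 on the log2 scale (SE, limma's adjusted p = 0.00154), and CG9757, CG7299 and Vajk2 were the other 3 genes that passed. Vajk2 measured 9.18 and 9.32 in juice replicates 1 and 2 and 7.08 in replicate 3, against 6.71 to 7.08 in control. CG32241 and the neuropeptide-like gene Nplp2 followed the same pattern, Nplp2 with 9.92 and 9.10 against 6.76 in replicate 3 and 6.17 to 6.76 in control.

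Large values on the control side came in part from control replicate 3. The tyrosine hydroxylase gene ple measured 10.04 there, against 7.31 and 8.39 in the other control arrays and 4.28 and 5.92 in palm fruit juice replicates 2 and 3, with juice replicate 1 the next highest. CG9822 measured 8.51 there and 2.67 to 4.54 in all other arrays. The nuclear receptor gene Hr4, at 7.83, and the scavenger receptor gene santa-maria, at 7.03, were also highest in that array.

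Oxidative phosphorylation, glycolysis, citric acid cycle and muscle genes together, 88 genes of which 79 were higher, had a mean log2 difference of 0.33, with array means of 0.26 and 0.37 in palm fruit juice replicates 1 and 2 and -0.14 in replicate 3. These lists were pooled after camera had called them higher, so the count and the mean follow from that choice and are no further support. Removing the trend with gene length left 0.33 (97.8% to 100.8% of the value with any array left out), so a length trend in the group difference does not account for it. That trend was small (Spearman's rho = -0.086). Relative to the mean of the other arrays, juice replicates 1 and 2 followed gene length with rho = 0.22 and -0.33. Each of these arrays is part of the reference of the other, so the opposite signs are partly built in. A length trend within single arrays was not tested for these lists and stays open. Larvae at another stage, read from the ecdysone response genes, remain a candidate explanation: with that score as a covariate the difference was 0.17, but between -0.26 and 0.38 with 1 array left out, so stage and juice cannot be told apart on 6 arrays. Across arrays the 2 scores had r = -0.75 (exact permutation p = 0.0597) and Spearman's rho = -0.77 (exact permutation p = 0.103). Both scores come from lists called for opposite differences between the groups, so a negative r is partly built in, and the permutation ignored the groups. Within the 3 control arrays r was -0.72 and within the 3 juice arrays -0.47. It was -0.34 without juice replicate 2 and -0.69 to -0.93 without any other single array, so that the relation leaned on juice replicate 2. Without juice replicate 2 and control replicate 3 together r was -0.14. Without juice replicate 2 the difference was 0.23, and 0.03 to 0.43 with a further array left out, so a part of that array alone and an effect of the juice itself both stay open.

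Testis genes stood higher in control replicate 1 than in the mean of the other arrays for 28 of 28 genes, by a median of 1.06 on the log2 scale; 1 of them, twe, is also in the DNA replication list. The brightest, S-Lap2, measured 8.74 there against 5.82 to 7.59 elsewhere, and betaTub85D 7.96 against 5.49 to 7.20. The median distance over all tested genes was 0.0082, but RMA holds that value near 0, so it decides nothing about a shift of the whole array. More males in that pool of 3 to 4 larvae could raise these genes, and roX1 and roX2, which males make, stood 0.28 above the other arrays, but between -0.12 and 0.79 when each other array was taken alone. The number of males therefore cannot be told apart from other causes, such as larger testes in older males, which were not tested.

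Ecdysone response and nervous system genes were lowest in palm fruit juice replicate 2, at -0.71 and -0.79 relative to the other arrays' mean. On the same measure, expression in that array also followed gene length (Spearman's rho = -0.33 across genes, which are not independent replicates). The rho of the other arrays was 0.05 to 0.22, but their reference includes juice replicate 2, which pushes these values up. Removing the length trend of that array left distances of -0.52 for ecdysone response and -0.53 for nervous system genes, 62.3% to 80.5% and 59.0% to 70.5% of the uncorrected ones against each other array in turn. The trend with gene length, as fitted over all genes, is therefore unlikely to be the whole cause, though it may account for a part. A trend with transcript length was not tested and stays open. An effect of the juice in that pool and a difference of stage stay open and were not tested.

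The 6 arrays form 10 splits into 3 and 3, the real one included, too few for a share under 0.05. The real split gave 0 genes past limma's adjusted p and the highest of the others 0, and any split reaches a count of 0, so this comparison says nothing. At unadjusted p the real split gave 470 genes and the highest other 612, with 5 of 10 splits at least as large. Camera with preset correlation called 9 lists in the real split and 18 in the highest other, which grouped palm fruit juice replicates 1 and 2 with control replicate 3, and 6 of 10 splits called at least as many. The number of lists called therefore does not set juice against control apart from other groupings. Small p-values of camera with preset correlation are on their own no evidence of an effect of the juice.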
